A study of Mus musculus with 25 samples.

How the data were processed

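Expression was measured in gonadal white adipose tissue of 25 male heterozygous ApoE3L.CETP mice on Affymetrix Mouse Gene 2.0 ST arrays, 1 mouse per array, per the labels. The authors processed the arrays in the Transcriptome Analysis Console, version 4.0.2, per the design text, which also names an analysis of variance of diet and time with a p under 0.05 and an absolute fold change of at least 1.5. Background correction, summarisation and normalization between arrays are not given in the sources used here. The deposited values were on the log2 scale, judged from their range of 1.73 to 14.13, since natural or decimal logarithms of that size would exceed what a scanner records. The table held 34472 transcript clusters, 1 column per array, and all columns were assigned to a group. Raw intensity files were not used here.

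Of the clusters, 25335 had an entry in the gene table, 23521 of them with 1 gene symbol, 1814 with several; the other 9137 had none. Where a symbol had more than 1 cluster (1082 genes), the cluster with the highest mean over the 25 arrays stood for the gene, which gave 22180 genes; clusters with several symbols or none were left out. Groups followed the labels: chow (2 arrays), LFD at 4, 8 and 12 weeks (4 each) and HFD at 4 weeks (3), 8 weeks (4) and 12 weeks (4). The labels give 34 weeks as the age of the 12-week groups, so comparisons use time on diet. Limits from precision follow from 2 to 4 arrays a group and 18 residual degrees of freedom.

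Differences were tested with limma 3.58.1 in R 4.3.3: 7 group means were fitted to the values of all 25 arrays and contrasts were tested with limma's moderated test, using the default prior. The comparisons were HFD against LFD at each time and averaged over the 3 times with equal weights, the interaction of diet and time as a moderated F over 2 differences, 8 and 12 weeks against 4 weeks within each diet, and each diet's mean over time against chow. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. No filter on intensity was applied. A difference is a log2 fold change ± its moderated standard error. For a diet comparison at 1 time, groups were called separated when no array of one lay within the range of the other.

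Gene lists were tested with camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry. Before the data were examined, 39 lists (605 genes, 546 measured) and a panel of single genes were fixed, and 24 panel genes were used here. Lists with at least 5 measured genes (38) were tested, and p values were adjusted over the lists of a comparison. Numbers of called list members are given from the test over all genes, and again with p values adjusted over the list alone. Lists for hepatocytes, liver macrophages, genes with a sex bias in liver and Y-linked genes were written after liver transcripts had been noticed.

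The genes named were chosen by a rule fixed before the data were examined. For diet comparisons it took the panel, the 8 called genes with the largest rise and the 8 with the largest fall among those with separated groups (for the average, with the same sign at all 3 times), and up to 4 called members with the smallest p of each list described. For time and chow comparisons it took the 5 called genes with the largest rise and the 5 with the largest fall, and for the interaction the 8 called genes with the smallest p. Where none were called, the 3 genes with the smallest p are given as values. Predicted genes and genes with provisional names were counted and not named.

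On simulated data with the real arrays' spread, the fit was tested on 22180 genes, of which 67 were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold. At 4 weeks it recovered 38.8%, 83.6% and 98.5% of them in that order, at 8 weeks 47.8%, 86.6% and 97.0%, and at 12 weeks 53.7%, 88.1% and 98.5%. False calls made up 8% of calls at 4 weeks, 2.35% at 8 weeks and 5.38% at 12 weeks. The calls counted there include genes of the macrophage list, which was also raised 2-fold for the list test. In the simulated list test the shifted list was called at each time, and 0 other lists were called. Genes were drawn independently of each other there, so the simulation does not test the list p values for correlated genes.

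Alternatives fixed beforehand were a fit of the compared groups alone, quantile normalization, centring on array medians, leaving out genes with a mean under 5.13, testing all clusters, the mean of a gene's clusters, intensity trend with robust moderation, array weights, replicate number as a block, an added fold limit of 1.5, the analysis of variance of the design text with and without adjustment, fry and an estimated correlation for lists, and leaving out each array in turn. After the data had been seen, these were added: the split into arrays with and without high hepatocyte transcripts as a block, the hepatocyte and epididymis means as covariates, leaving out chow array 1, LFD 4-week array 1 and HFD 4-week array 1 together, that removal combined with the block, and fits on either side of the split. Single arrays were compared with the rest of their group where it held 4 arrays, by the gap to the nearest array over the range, against Dixon's 95% limit for 4 values. Other divisions of the arrays were fitted in full up to 35, or as a draw of 100.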

Results

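Gonadal white adipose tissue was profiled in male ApoE3L.CETP mice, which carry the APOE*3-Leiden variant and the human cholesteryl ester transfer protein and serve as a model of humanised lipoprotein metabolism. Mice received a low-fat diet (LFD) or a high-fat diet with added cholesterol (HFD) from the age of 12 weeks, and tissue was taken after 4, 8 or 12 weeks. A further group on chow was sampled at the start. Each of the 25 arrays measured 1 mouse. The groups held 2 chow arrays, 4 LFD and 3 HFD arrays at 4 weeks, and 4 LFD and 4 HFD arrays at both 8 and 12 weeks. The age given in the labels was 34 weeks for the 12-week groups, whereas 12 weeks of diet from the age of 12 weeks would give a lower age, so the time on diet is used here. Array medians lay between 5.04 and 5.36 on the log2 scale, and pairs of arrays correlated between 0.889 and 0.993 across transcript clusters. Levels below are array values on the log2 scale as mean ± SD, and differences are log2 fold changes ± standard error from limma. The number of arrays, 2 to 4 in a group, limits the precision.

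Transcripts of other tissues were present in part of the arrays. The mean of 28 hepatocyte genes, a list written after the data were examined, lay between 9.12 and 11.08 in 11 of the 16 arrays taken at 8 and 12 weeks and at 7.15 or below in the other 14 arrays. These 11 arrays were LFD 8-week arrays 1 and 2, HFD 8-week arrays 2, 3 and 4, LFD 12-week arrays 1, 2 and 4, and HFD 12-week arrays 1, 2 and 4. Albumin (Alb) reached 12.96 to 13.62 in them. Xist, the RNA that silences an X chromosome in female cells, lay between 5.03 and 6.76 in the same 11 arrays and at 3.92 or below in the others, although all mice were labelled male. The mean of 13 epididymis genes, a list fixed beforehand, was 11.89 in chow array 1, 10.22 in HFD 4-week array 1, 5.67 in LFD 4-week array 1 and at most 4.06 elsewhere. LFD 4-week array 1 also had the highest median (5.36) and a mean correlation of 0.957 with the other arrays. Among the 25 arrays, the first principal component held 32.6% of the variance and placed the 11 arrays with hepatocyte transcripts at scores of 19.7 to 40.1, above all others. Of the 28 hepatocyte genes, 16 were also above the median cluster level in the 14 arrays without high hepatocyte transcripts. These 14 were not even. Their hepatocyte mean was 7.15 in LFD 12-week array 3, 6.88 in LFD 4-week array 1, 6.72 in HFD 4-week array 1 and 6.52 in HFD 8-week array 1. In the rest of them it was at most 5.59.

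**Figure D1:**
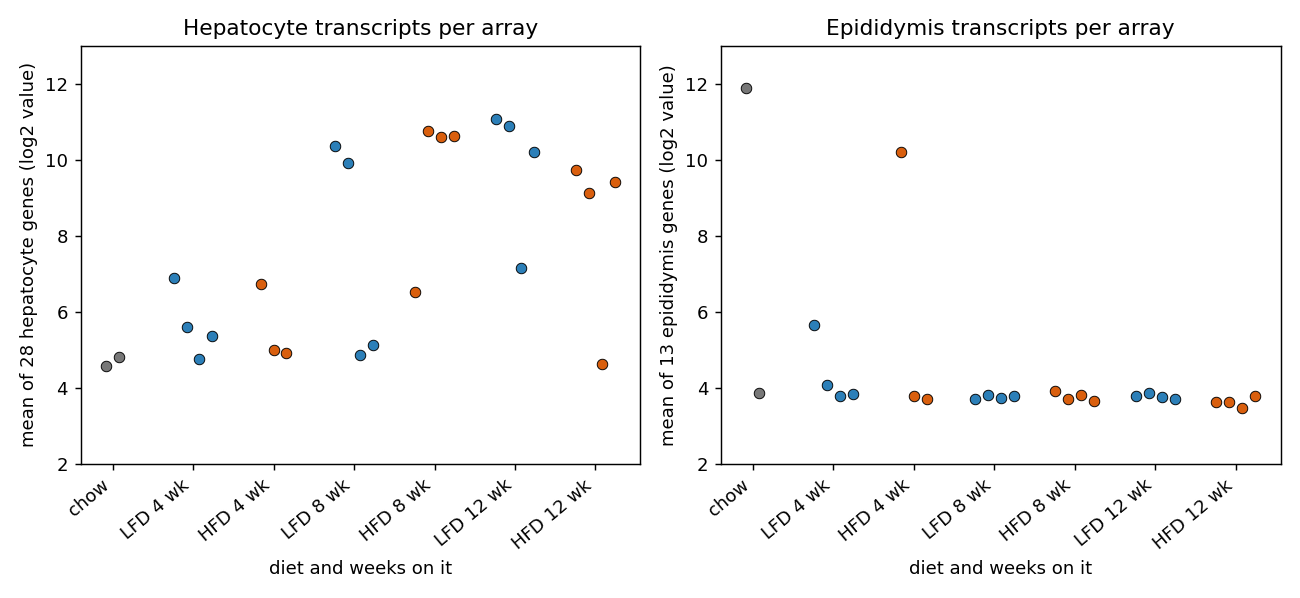
Mean log2 value of 28 hepatocyte genes (left) and 13 epididymis genes (right) in each array, by diet and weeks on it; each point is 1 array. Hepatocyte means of 9.12 to 11.08 appear in 11 arrays at 8 and 12 weeks of both diets, and epididymis means of 11.89 and 10.22 in chow array 1 and HFD 4-week array 1.

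The first question was which transcripts differed between HFD (n = 3) and LFD (n = 4) after 4 weeks. The most raised named gene was Sfrp5, a secreted Wnt antagonist of adipocytes (3.59 ± 0.59), from 5.82 ± 1.19 under LFD to 9.41 ± 0.91 under HFD. The cell cycle inhibitor gene Cdkn1a rose by 2.40 ± 0.30 (adjusted p = 0.00126). Rnase2a, an eosinophil-type ribonuclease (2.97 ± 0.52), Slc5a7, the high-affinity choline transporter (2.89 ± 0.46), Hspb7, a small heat shock protein (2.37 ± 0.39), Fgf13 (1.89 ± 0.30) and Ighm (1.72 ± 0.34) also rose, where Ighm was at 0.03 and not called as the mean of its clusters. Angpt1, the ligand of the endothelial Tie2 receptor, fell by 2.01 ± 0.36. The other falls were Sugct (−1.33 ± 0.26), Rnf144b (−1.07 ± 0.19), Net1 (−1.04 ± 0.17) and Cp (−0.94 ± 0.19), where Cp encodes ceruloplasmin.

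Among 11 measured markers of adipocyte expansion, 3 rose at 4 weeks (6 adjusted over the list alone) and none fell. They were Sfrp5, Mest, an imprinted gene induced in enlarging fat cells (1.71 ± 0.27), and Bmp3 (1.79 ± 0.28), and the list was called by camera (adjusted p = 1.68e-06; adjusted p = 0.0919 with an estimated correlation). Of 27 extracellular matrix genes, 4 rose (16 adjusted over the list alone). These were the collagen VI chains Col6a1 (1.18 ± 0.19), Col6a2 (1.00 ± 0.19) and Col6a3 (0.92 ± 0.17), with Postn, which encodes the matrix protein periostin (1.32 ± 0.22). The list had adjusted p = 1.08e-17, and adjusted p = 0.0919 with an estimated correlation. Hmgcs1, which makes the precursor of mevalonate, rose by 1.04 ± 0.14, as 1 of 18 genes of cholesterol synthesis, and Edem1, of endoplasmic reticulum quality control, rose by 0.65 ± 0.12. No gene of de novo lipogenesis passed the test over all genes, and 5 of 18 were lower when adjusted over the list alone. The list's median was −0.46 (adjusted p = 8.72e-09; adjusted p = 0.113 with an estimated correlation), with Fasn at −0.47 ± 0.24 and Scd1 at −0.14 ± 0.09. Fasn was at −0.81 and called without the 3 arrays that stood apart, at −0.76 and called with array weights, and at −0.79 without LFD array 1 and −0.30 without LFD array 4, both uncalled. No gene of the 2 macrophage lists passed the test, with Itgax at 0.77 ± 0.35. The chemokine gene Ccl2 (1.33 ± 0.39) and Lep, the satiety hormone leptin (0.66 ± 0.24), were not called at 4 weeks, although both passed the analysis of variance with unadjusted p. Ccl2 was called with the hepatocyte and epididymis means as covariates (1.49) and was at 0.76 without HFD array 3.

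In all, limma called 47 of 22180 genes at 4 weeks after Benjamini-Hochberg adjustment, 42 higher and 5 lower under HFD, and 2069 had an unadjusted p under 0.05. The arrays of the diets did not overlap for 2016 of the 22180 genes, a separation that chance gives in 5.71% of unchanged genes at these group sizes. Of 38 lists, 9 were called up and 4 down by camera, and 0 with an estimated correlation. The count was sensitive to single arrays: it was 2 without HFD array 3, 27 without HFD array 1, 29 without HFD array 2, 30, 100, 29 and 24 without LFD arrays 1, 2, 3 and 4, and 0 when these 7 arrays were fitted alone. Hmgcs1 and Cdkn1a stayed called whichever array was left out, and the other 18 of the 20 called genes chosen for naming did not. HFD 4-week array 1 and LFD 4-week array 1 were the arrays with epididymis transcripts, and the epididymis list had a median of 1.73 (adjusted p = 0.00275; adjusted p = 0.735 with an estimated correlation). Without these arrays and chow array 1, 66 genes were called, 29 of the 47 among them, and the epididymis median was −0.10.

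After 8 weeks (n = 4 and 4), genes of lipid synthesis were lower under HFD. Acaca, the cytosolic acetyl-CoA carboxylase that commits acetyl-CoA to fatty acid synthesis, fell by 2.31 ± 0.27 (adjusted p = 2.13e-04), from 12.06 ± 0.22 under LFD to 9.76 ± 0.28. Other falls were the fatty acid elongase gene Elovl6 (−2.48 ± 0.56), ATP citrate lyase gene Acly (−2.11 ± 0.43), Acss2 (−1.96 ± 0.36), Acacb (−1.91 ± 0.36) and Fasn (−1.31 ± 0.22). Of 18 de novo lipogenesis genes, 12 fell and none rose (16 lower adjusted over the list alone), with a median of −1.01 (adjusted p = 5.19e-21; adjusted p = 0.0133 with an estimated correlation). Mlxipl, which encodes the carbohydrate-sensing regulator ChREBP, fell by 1.10 ± 0.21. Scd1 (−0.28 ± 0.09) and Srebf1 (−0.70 ± 0.23) did not pass the test, but both were called without the 3 arrays that stood apart and with array weights. The insulin-responsive glucose transporter gene Slc2a4 fell by 1.08 ± 0.23, while Adipoq was at −0.07 ± 0.16 and Pparg at −0.50 ± 0.24, of which Pparg was called in those 2 fits. Elovl6 lost its call without HFD array 1 or LFD array 4, and Slc2a4 without HFD array 1.

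At 8 weeks, of 20 oxidative phosphorylation genes, 4 fell (17 adjusted over the list alone), among them Sdha (−0.56 ± 0.12), Ndufb8 (−0.53 ± 0.13) and Cyc1 (−0.59 ± 0.16) (adjusted p = 1.27e-14; adjusted p = 0.0238 with an estimated correlation). Of 18 genes of branched-chain amino acid catabolism, 4 fell (11 adjusted over the list alone), as Mccc1 (−0.95 ± 0.18) and Ivd (−0.87 ± 0.20); the list had adjusted p = 4.01e-12 and adjusted p = 0.0994 with an estimated correlation. The cholesterol synthesis list split: 4 of 18 genes fell, including Fdft1 (−0.99 ± 0.19), Pmvk (−1.02 ± 0.21) and Cyp51 (−1.33 ± 0.29), whereas Hmgcs1 rose by 0.73 ± 0.13 (adjusted p = 7.5e-07; adjusted p = 0.194 with an estimated correlation). Cyc1 lost its call whichever array was left out, Ndufb8 without 7 of the 8 arrays, and Sdha, Ivd and Cyp51 without 3.

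At 8 weeks, among markers of lipid-associated macrophages, the foam-like cells that gather around dying fat cells, 7 of 15 rose (9 adjusted over the list alone): Mmp12 (2.86 ± 0.50), Atp6v0d2 (2.75 ± 0.66), Gpnmb (2.63 ± 0.55) and Itgax (1.75 ± 0.33) were the most raised, and Trem2 rose by 1.43 ± 0.37. The list had a median of 0.81 (adjusted p = 4.4e-09; adjusted p = 0.078 with an estimated correlation). Of 20 general macrophage genes, 7 rose (15 adjusted over the list alone), such as Cd68 (1.16 ± 0.30), Itgam (0.92 ± 0.22) and Adgre1 (0.87 ± 0.22) (adjusted p = 1.28e-12; adjusted p = 0.0795 with an estimated correlation). HFD array 1 stood apart for Trem2 (9.32, the next HFD array 7.25), and without it Trem2 was at 0.88. Trem2, Atp6v0d2, Cd68, Itgam and Adgre1 were not called without that array, nor without LFD array 1, 2 or 4. Cytokine and acute-phase genes rose in 7 of 23 cases, including the serum amyloid gene Saa3 (2.08 ± 0.37), Il1rn (1.33 ± 0.21) and the monocyte attractant gene Ccl2 (1.47 ± 0.36), with adjusted p = 2.13e-10 and adjusted p = 0.0221 with an estimated correlation. Ciita and H2-Ab1, of antigen presentation by MHC class II, rose by 0.87 ± 0.15 and 0.71 ± 0.19 (adjusted p = 4.39e-07; adjusted p = 0.0238 with an estimated correlation). H2-Ab1 lost its call whichever array was left out, Ccl2 without 6 of the 8 arrays, and Thbs1, named next, without LFD array 1 or 2. In the matrix list 6 of 27 genes rose (12 adjusted over the list alone), with Thbs1 (2.10 ± 0.46), Timp1 (1.46 ± 0.26) and Postn (1.37 ± 0.20) (adjusted p = 3.72e-13; adjusted p = 0.078 with an estimated correlation). Sfrp5 (4.04 ± 0.55), Slc5a7 (3.75 ± 0.43), Peg3 (2.83 ± 0.47), Ubd (2.52 ± 0.49) and Mest (1.42 ± 0.25) rose as well.

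limma called 533 genes at 8 weeks, 259 higher and 274 lower under HFD. The diets' arrays did not overlap for 2534 of the 22180 genes tested, which chance gives in 2.86% of unchanged genes. High hepatocyte transcripts were present in 3 of the 4 HFD arrays and 2 of the 4 LFD arrays. With that split of the arrays as a block, 689 genes were called, 504 of the 533 among them. With the hepatocyte and epididymis means as covariates 970 were called, 499 of the 533 among them. The 81 called genes chosen for naming at 8 weeks stayed called in both fits, and 39 of them whichever single array was left out. The count fell to 164 without HFD array 1 and to 251, 228, 297 and 331 without LFD arrays 1, 2, 3 and 4. It was 1251 without the 3 arrays of the chow and 4-week groups that stood apart, since these arrays enter the shared estimate of the spread, and 152 of the 533 stayed called among 211 when only arrays with high hepatocyte transcripts were used.

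**Figure D2:**
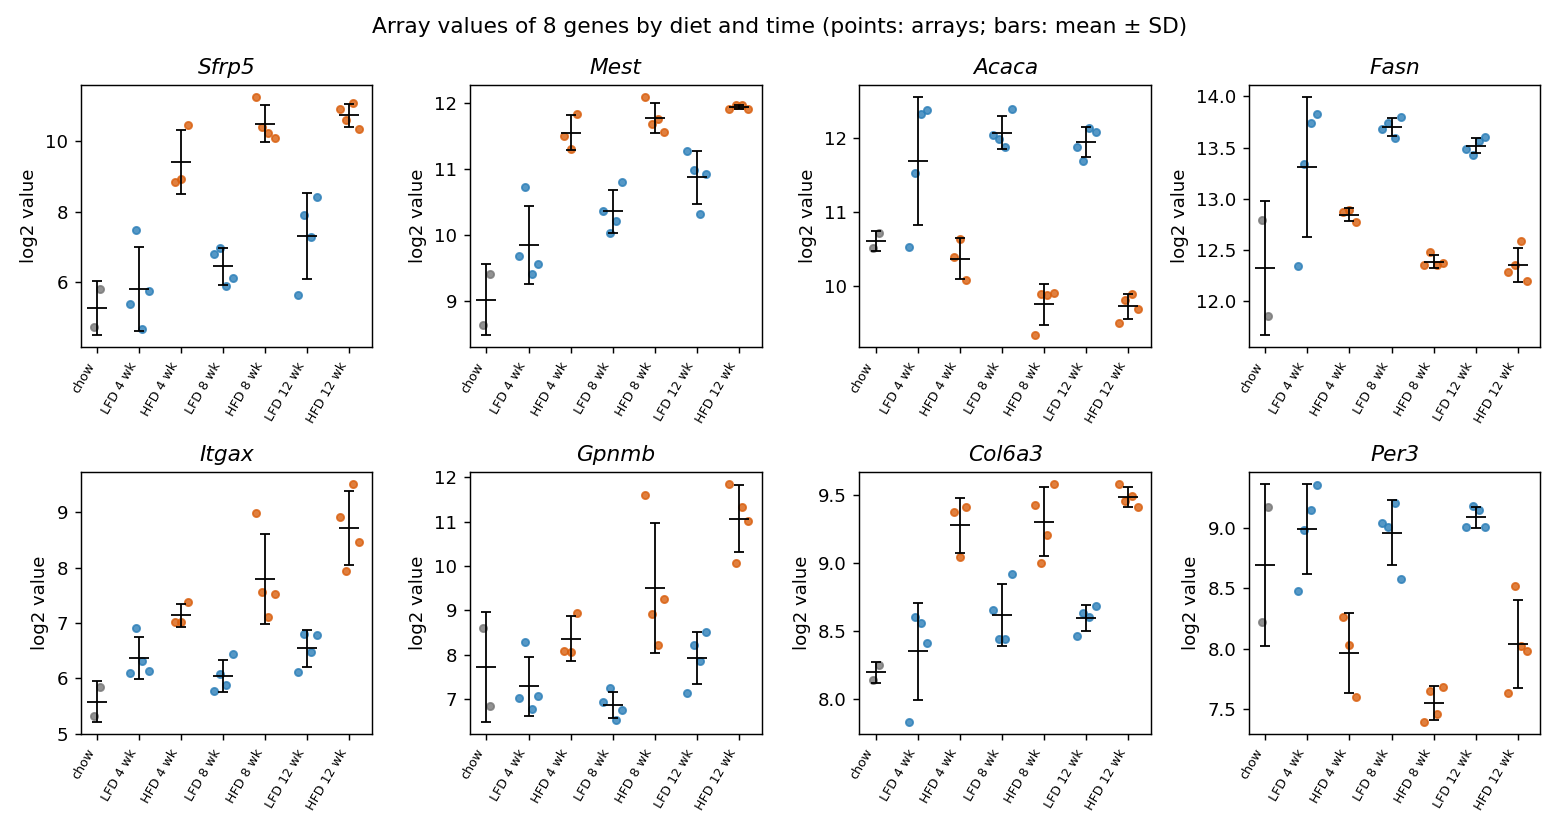
Array values on the log2 scale of 8 genes by diet and weeks on it; points are arrays, bars the mean ± SD of 2 to 4 arrays. Sfrp5 averaged 6.45 ± 0.53 under LFD and 10.49 ± 0.52 under HFD at 8 weeks, and Acaca 12.06 ± 0.22 and 9.76 ± 0.28.

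After 12 weeks (n = 4 and 4), the largest rises were Slc5a7 (3.89 ± 0.43), Sfrp5 (3.42 ± 0.55), the lysosomal proton pump subunit gene Atp6v0d2 (3.20 ± 0.66) and Gpnmb, a glycoprotein of lipid-laden macrophages (3.14 ± 0.55). Gpnmb went from 7.93 ± 0.59 under LFD to 11.07 ± 0.75 under HFD. Of 20 macrophage genes, 15 rose and none fell (17 adjusted over the list alone), among them Cd68 (1.78 ± 0.30), Tyrobp (1.58 ± 0.26), Itgam (1.36 ± 0.22) and Laptm5 (1.23 ± 0.19), and the list's median was 0.92 (adjusted p = 1.44e-17; adjusted p = 0.0397 with an estimated correlation). Of 15 lipid-associated macrophage markers, 9 rose, with Trem2 (2.23 ± 0.37), Itgax (2.17 ± 0.33), Ctsk (1.81 ± 0.31) and Lgals3 (1.20 ± 0.21) (adjusted p = 3.24e-12; adjusted p = 0.0397 with an estimated correlation). Lysosome genes rose in 9 of 21 cases, such as cathepsin S (Ctss, 1.74 ± 0.28) and lysosomal acid lipase (Lipa, 0.99 ± 0.18), with adjusted p = 2.53e-10 and adjusted p = 0.0607 with an estimated correlation. MHC class II presentation genes rose in 5 of 10 cases, as H2-Ab1 (1.05 ± 0.19), H2-Eb1 (0.96 ± 0.19) and H2-Aa (0.86 ± 0.19) (adjusted p = 1.85e-06; adjusted p = 0.0357 with an estimated correlation). Cytokine genes rose in 8 of 23 cases, with Saa3 (2.15 ± 0.37), Ccl2 (1.36 ± 0.36) and Ccl8 (1.29 ± 0.28), while Tnf was at 0.63 ± 0.18 (adjusted p = 0.0532). That list had adjusted p = 2.39e-08, and adjusted p = 0.0357 with an estimated correlation. The genes Il7r (2.74 ± 0.40), Tm4sf19 (2.73 ± 0.49) and Ubd (2.66 ± 0.49) were also among the most raised.

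Matrix and proliferation genes were higher at 12 weeks. Of 27 matrix genes, 18 rose and none fell (24 adjusted over the list alone): examples were Postn (1.38 ± 0.20), Col6a1 (1.20 ± 0.18), Col6a2 (1.07 ± 0.17) and Timp1 (1.35 ± 0.26) (adjusted p = 4.9e-23; adjusted p = 0.0357 with an estimated correlation). Of 19 cell cycle genes, 11 rose (18 adjusted over the list alone), with the proliferation marker Mki67 at 1.25 ± 0.22 and the spindle motor gene Kif11 at 0.88 ± 0.14 (adjusted p = 7.8e-17; adjusted p = 0.0357 with an estimated correlation). Among cholesterol efflux genes Pltp (1.22 ± 0.19) and Abcg1 (1.09 ± 0.21) rose, 2 of 10, with no call of the list (adjusted p = 0.117).

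At 12 weeks, in the de novo lipogenesis list 13 of 18 genes fell and none rose, with a median of −1.16 (adjusted p = 2.54e-20; adjusted p = 0.0168 with an estimated correlation): Elovl6 (−2.38 ± 0.56), Acaca (−2.21 ± 0.27), Acacb (−1.93 ± 0.36) and Acly (−1.81 ± 0.43) fell most, and Fasn (−1.16 ± 0.22) and Mlxipl (−1.15 ± 0.21) fell too. Oxidative phosphorylation genes fell in 4 of 20 cases (17 adjusted over the list alone), as Cox5b (−0.55 ± 0.12) and Uqcrc2 (−0.52 ± 0.12) (adjusted p = 6.89e-12; adjusted p = 0.0397 with an estimated correlation). As the mean of its clusters Cox5b was at −0.26 and not called, and its call was lost without HFD array 3. Branched-chain amino acid genes fell in 3 of 18 cases (14 adjusted over the list alone), with Ivd (−0.84 ± 0.20) and Echs1 (−0.61 ± 0.14) (adjusted p = 3.39e-11; adjusted p = 0.14 with an estimated correlation). Of 15 mature adipocyte genes, 3 fell: Nat8l (−1.46 ± 0.28) and Rbp4 (−0.74 ± 0.19) and Slc2a4, which fell by 1.00 ± 0.23. Adipoq, which encodes adiponectin, was at −0.02 ± 0.16, and the list had adjusted p = 0.00138 and adjusted p = 0.415 with an estimated correlation. In the insulin signalling list Slc2a4 and Pik3r1 (−0.87 ± 0.15) fell, 2 of 15 (adjusted p = 0.00542; adjusted p = 0.415 with an estimated correlation). Angpt1 (−1.69 ± 0.33, or −1.07 as the mean of its clusters), Fam13a, near a locus tied to body fat distribution (−1.94 ± 0.38), and Cldn22 (−1.74 ± 0.27) fell.

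At 12 weeks limma called 989 genes, 695 higher and 294 lower under HFD, and the diets' arrays did not overlap for 2795 of the 22180 genes against 2.86% of unchanged genes by chance. Both diets had 3 of 4 arrays with high hepatocyte transcripts, at hepatocyte means of 10.22 to 11.08 under LFD and 9.12 to 9.74 under HFD. With the split as a block 1457 genes were called, all 989 among them, and with the covariates 1089, 897 of the 989 among them. The block has 2 levels, so it does not take up the difference in hepatocyte means between the diets. Genes lower under HFD numbered 638 with the block and 380 with the covariates. The 92 called genes chosen for naming stayed called in both fits, and 66 of them whichever single array was left out. Ccl2 and Rbp4 lost their calls without 5 of the 8 arrays, Uqcrc2 and Ivd without 2, and Slc2a4, Elovl6 and Acly without 1. The count was 638 without HFD array 1, 598 without HFD array 3, 558 without LFD array 1 and 1865 without the 3 arrays of other groups that stood apart. The mesothelium list had a median of −0.54 with 0 of 12 genes called (adjusted p = 0.00139; adjusted p = 0.3 with an estimated correlation), and the endothelial list had a median of 0.08 (adjusted p = 0.409).

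**Figure D3:**
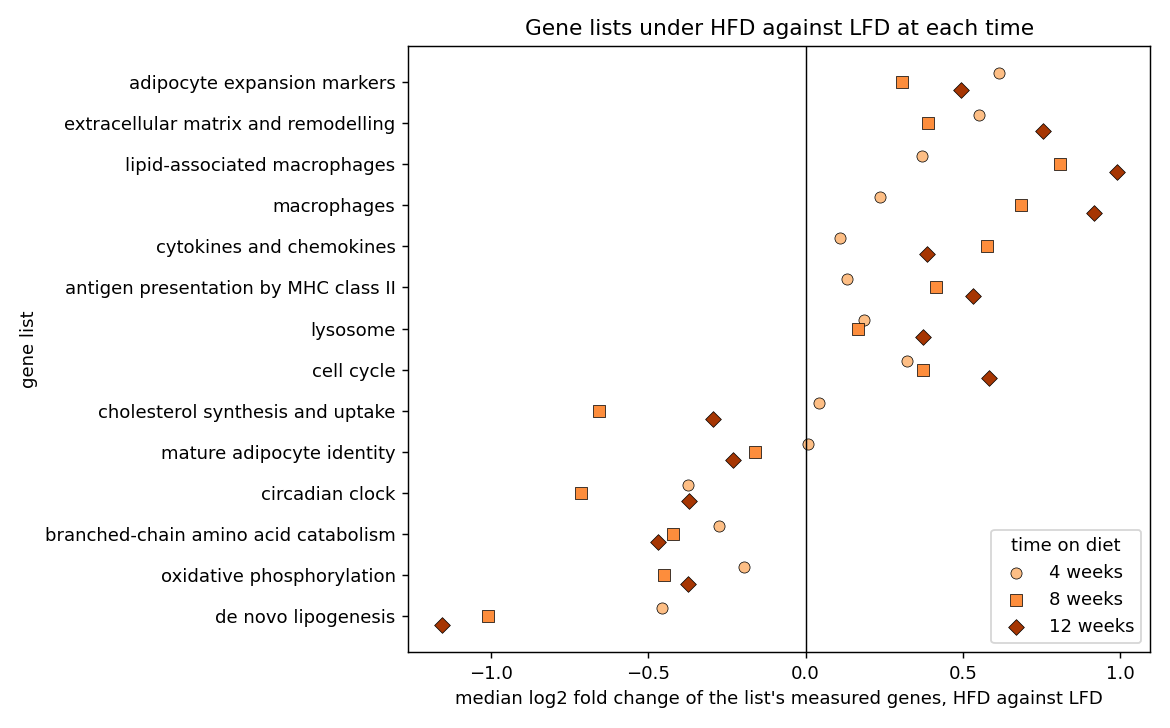
Median log2 fold change, HFD against LFD, of the measured genes of 14 lists fixed before the data were examined, at 4, 8 and 12 weeks; each point is the median of 1 list at 1 time. The de novo lipogenesis medians were −0.46, −1.01 and −1.16, and the macrophage medians 0.24, 0.69 and 0.92.

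Averaged over the 3 times (11 HFD and 12 LFD arrays), the diet difference took in more genes. Lep rose by 0.57 ± 0.13 (adjusted p = 0.00514) and Tnf by 0.47 ± 0.11, and neither was called at a single time. Without the 3 arrays that stood apart, however, both were called at 12 weeks. Tnf was called there also without HFD array 4 or LFD array 4, with the hepatocyte split as a block and in 4 other alternatives fixed beforehand. At 8 weeks Tnf was called with the hepatocyte split as a block and with the covariates. Srebf1, a master regulator of lipid synthesis, fell by 0.51 ± 0.14 and Scd1, the stearoyl-CoA desaturase gene, fell by 0.19 ± 0.05, but Scd1 was at −0.12 and not called with quantile normalization, and not called without HFD 4-week array 1. Cyp2f2, a cytochrome P450 gene of lung and liver, was at −2.14 ± 0.43, and at −1.27 as the mean of its clusters. Adipoq (−0.03 ± 0.09), Pparg (−0.33 ± 0.14), Insr (−0.28 ± 0.09), Ucp1 (0.07 ± 0.08), Apoe (−0.17 ± 0.09) and Sqle (−0.38 ± 0.19) were not called, with adjusted p from 0.0603 to 0.931, but Pparg, Insr and Sqle were called without the 3 arrays that stood apart. Lists with most members called were the matrix list (22 of 27 up; adjusted p = 0.0282 with an estimated correlation), cell cycle (15 of 19 up; adjusted p = 0.0282 with an estimated correlation), macrophages (16 of 20 up and 1 down; adjusted p = 0.0566 with an estimated correlation), oxidative phosphorylation (16 of 20 down; adjusted p = 0.0282 with an estimated correlation), branched-chain amino acid catabolism (13 of 18 down; adjusted p = 0.0683 with an estimated correlation) and de novo lipogenesis (15 of 18 down; adjusted p = 0.0109 with an estimated correlation). Adjusted over the list alone, these counts were 26, 19, 17 and 1, 19, 18 and 16. limma called 2322 genes, 1338 higher and 984 lower, of which 2242 had the same sign at all 3 times and 596 differed at least 1.5-fold. The count was 2505 with the hepatocyte split as a block, 2957 without the 3 arrays that stood apart, and between 1793 and 2527 when single arrays were left out. Of the 119 called genes chosen for naming, 106 stayed called whichever array was left out.

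The diet comparisons at the 3 times used different mice. Of the genes higher under HFD, 33 were called at both 4 and 8 weeks against 0.490 expected for independent lists, 37 at 4 and 12 weeks against 1.32, and 213 at 8 and 12 weeks against 8.12. Of the lower genes, 122 were called at both 8 and 12 weeks against 3.63, and no gene was called in opposite directions at any pair of times. Sfrp5, Slc5a7, Rnase2a, Cdkn1a, Mest, Postn, Col6a1 and Hmgcs1 were among the 31 genes higher at all 3 times, and 3 genes were lower at all 3. The interaction of diet and time, tested with limma's moderated F over 23 arrays, called 0 genes, with 1199 at an unadjusted p under 0.05 and a smallest adjusted p of 0.856, and the analysis of variance without moderation also called 0 after adjustment. So no gene's diet effect was shown to differ between times. The 3 genes with the smallest p were Col6a5, Fam110c and Ifi209, whose diet effects differed between times by at most 2.65, 0.74 and 1.71. With the hepatocyte split as a block the interaction called 81 genes, Col6a5 and Ifi209 among them, of which 70 were genes raised by over 1 in the arrays with high hepatocyte transcripts, as only 1.57% of all genes were. With the hepatocyte and epididymis means as covariates it called 0.

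Time on LFD was compared with the 4-week group (n = 4 each). At 8 weeks the mevalonate pathway genes Pmvk (1.00 ± 0.21) and Mvd (0.90 ± 0.21) rose, 2 of 18 genes of cholesterol synthesis (12 adjusted over the list alone; adjusted p = 5.69e-10; adjusted p = 0.379 with an estimated correlation). Also raised were Wdr46 (0.98 ± 0.19), Adcy10 (0.95 ± 0.21) and Igfals (0.98 ± 0.22), the last a liver gene for an insulin-like growth factor carrier. Falls were Col6a5 (−1.40 ± 0.32), Fam205a2 (−1.12 ± 0.25), Speer4d (−0.97 ± 0.21), Grem1 (−0.96 ± 0.19) and Rps15 (−0.91 ± 0.20). At 12 weeks on LFD the raised genes were Cyp2a4 (4.54 ± 1.05), Elovl3 (2.90 ± 0.65), Cyp2b13 (2.44 ± 0.53), Ppp1r3b (1.68 ± 0.39) and Hspb7 (1.56 ± 0.36), of which Cyp2a4, Cyp2b13 and Ppp1r3b are known from liver. Falls were the complement gene C7 (−1.91 ± 0.33), Col6a5 (−1.58 ± 0.32), Oog1 (−1.39 ± 0.21), Bmper (−1.34 ± 0.23) and Sult1e1 (−1.47 ± 0.34). The glutathione list was called up at 12 weeks (adjusted p = 0.0159; adjusted p = 0.346 with an estimated correlation), with 0 of 17 genes up. limma called 141 genes at 8 weeks (104 higher, 37 lower) and 151 at 12 weeks (66 higher, 85 lower). None of the 7 arrays at 4 weeks and 5 of the 8 later LFD arrays had high hepatocyte transcripts. With that split as a block, 33 and 19 genes were called, and fitted on their own groups 0 and 14. Centring each array on its median moved the median of all genes by 0.11 at 8 weeks and gave 252 higher and 24 lower genes there. C7, Oog1 and Bmper stayed called at 12 weeks whichever array was left out, and no gene named at 8 weeks did. With the hepatocyte split as a block, 1 of the 10 genes named at 8 weeks (Wdr46) and 2 of the 10 at 12 weeks (Cyp2a4 and Oog1) stayed called. With the hepatocyte and epididymis means as covariates, 8 of the 10 and 2 of the 10 (Oog1 and Bmper) did. None of the 5 rises at 12 weeks was called with the covariates, where Cyp2a4 was at 1.12, Elovl3 at 0.97, Cyp2b13 at 0.93, Ppp1r3b at 0.90 and Hspb7 at 1.46. Without the 3 arrays that stood apart, Wdr46 at 8 weeks and C7, Oog1 and Bmper at 12 weeks were called, and with the block added C7 fell by 1.25 and Speer4d, at 8 weeks, by 0.64, both without a call. Oog1 was at −0.64 and not called as the mean of its clusters, and was not called on its own groups. At 8 weeks the count was 52, 50 and 224 without LFD 4-week arrays 1, 3 and 4, and 24, 22, 84 and 34 without LFD 8-week arrays 1, 2, 3 and 4. At 12 weeks it was 50, 100 and 53 without LFD 4-week arrays 1, 2 and 3, and 49, 40, 639 and 28 without LFD 12-week arrays 1, 2, 3 and 4.

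Time on HFD was compared with the 4-week group (n = 3). At 12 weeks (n = 4) macrophage genes rose: Gpnmb (2.71 ± 0.59), Trem2 (1.87 ± 0.40) and Tlr13 (1.83 ± 0.35), together with Il7r (2.24 ± 0.43) and F7 (1.95 ± 0.36). Of 15 lipid-associated macrophage markers, 4 rose (10 adjusted over the list alone), with a median of 1.01 (adjusted p = 9.03e-11; adjusted p = 0.28 with an estimated correlation). The macrophage list had 1 of 20 up (11 adjusted over the list alone; adjusted p = 2.57e-10; adjusted p = 0.28 with an estimated correlation). Falls were Mmrn1 (−1.30 ± 0.28), Rhbdl1 (−1.27 ± 0.28), S100a1 (−1.21 ± 0.23), Oog1 (−1.20 ± 0.23) and Cytl1 (−1.17 ± 0.16). Of these 10 rises and falls, only that of Cytl1 stayed called whichever array was left out. Without the 3 arrays that stood apart, none of the 5 rises named here was called, nor the fall of Mmrn1, and each of the 5 also lost its call without any of 4 to 6 of the 7 arrays. Mmrn1 and Rhbdl1 were not called with the hepatocyte split as a block, and Oog1 was at −0.73 and not called as the mean of its clusters. At 8 weeks (n = 4) limma called 0 genes, with 1964 at an unadjusted p under 0.05, and the analysis of variance also called 0 after adjustment. The 3 genes with the smallest p were Cytl1 (−0.99 ± 0.16), Camk1d (0.86 ± 0.15) and Fam98b (0.58 ± 0.11), with adjusted p from 0.0587 to 0.112, and all 3 were called without the 3 arrays that stood apart. The interferon response list had a median of 0.33 at 8 weeks, with 0 of 17 genes called (adjusted p = 1.3e-08; adjusted p = 0.431 with an estimated correlation). limma called 127 genes at 12 weeks, 86 higher and 41 lower, and 213 with the hepatocyte split as a block. The count at 12 weeks was 13 and 4 without HFD 4-week arrays 1 and 2, 22, 17 and 39 without HFD 12-week arrays 1, 3 and 4, and 5 on its own groups. At 8 weeks it was 2 without HFD 4-week array 1, 1 without HFD 8-week array 2 and 15 without the 3 arrays that stood apart.

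Both diets were compared with the chow baseline (n = 2), averaged over the 3 times; age, diet and time differed together, and chow array 1 held the epididymis transcripts, while neither chow array had high hepatocyte transcripts. Under LFD (12 arrays) the prostaglandin E receptor gene Ptger3 rose by 2.92 ± 0.22 (adjusted p = 1.03e-07) and Mtarc1, a mitochondrial reductase gene, by 2.90 ± 0.34, and both stayed called whichever array was left out. The glycogen synthase gene Gys2 rose by 2.87 ± 0.49, and was not called with the hepatocyte and epididymis means as covariates, nor without chow array 1. Of 18 de novo lipogenesis genes, 11 rose against chow (14 adjusted over the list alone), with a median of 0.93 (adjusted p = 1.28e-09; adjusted p = 0.154 with an estimated correlation). That median was 0.74 with 8 genes up without the 3 arrays that stood apart. Of 17 fatty acid oxidation genes 10 rose (14 adjusted over the list alone; adjusted p = 3.39e-07; adjusted p = 0.502 with an estimated correlation), and 1 with the hepatocyte split as a block. The list of adipocyte expansion markers had 6 of 11 up (7 adjusted over the list alone; adjusted p = 5.22e-07; adjusted p = 0.0891 with an estimated correlation). The largest differences were transcripts of the other tissues: the liver genes Mup3 (5.99 ± 1.72) and Serpina1d (5.28 ± 1.59) were higher, and the epididymis genes Rnase9 (−4.67 ± 1.51), Pate6 (−4.46 ± 1.39), Defb12 (−4.44 ± 1.28), Muc15 (−4.41 ± 1.38) and Defb39 (−4.38 ± 1.35) were lower. With the covariates Mup3 was at 2.82, without a call, and Serpina1d at 1.80. Without chow array 1, Rnase9 was at 0.04, Pate6 at −0.18, Defb12 at −0.25, Muc15 at −0.08 and Defb39 at 0.005, and none of these 7 liver and epididymis genes was called.

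Under HFD (11 arrays) Sfrp5 was higher than on chow by 4.95 ± 0.59 (adjusted p = 1.47e-05), and it stayed called whichever array was left out. Of 11 adipocyte expansion markers, 7 rose (8 adjusted over the list alone; adjusted p = 2.4e-09; adjusted p = 0.0214 with an estimated correlation), and 7 did without the 3 arrays that stood apart. Of 20 macrophage genes, 16 rose (17 adjusted over the list alone; adjusted p = 1.52e-11; adjusted p = 0.187 with an estimated correlation), but 2 without those arrays. Matrix genes rose in 19 of 27 cases (21 adjusted over the list alone; adjusted p = 3.61e-12; adjusted p = 0.187 with an estimated correlation) and cell cycle genes in 12 of 19 (16 adjusted over the list alone; adjusted p = 1.22e-08; adjusted p = 0.187 with an estimated correlation), against 8 and 1 without them. The de novo lipogenesis list, with a median of 0.00 and a mean of −0.04, had 3 genes up and 1 down (adjusted p = 0.854). Liver genes were again higher, as Mup20 (6.15 ± 2.01), Mup3 (6.01 ± 1.73), Serpina1d (5.79 ± 1.60) and Alb (4.43 ± 1.51), and epididymis genes lower, as Defb12 (−3.82 ± 1.29), Defb38 (−3.58 ± 1.20), Lcn12 (−3.41 ± 1.13), Clpsl2 (−3.38 ± 1.14) and Lcn10 (−3.27 ± 1.03). With the hepatocyte and epididymis means as covariates Mup20 was at 2.80 and Alb at 2.11, both without a call, Mup3 at 2.66 and Serpina1d at 2.19. Mup20 and Alb lost their calls without 9 and 10 of the 13 arrays. Without chow array 1 these epididymis genes were at 0.37, 0.32, 0.12, 0.26 and 0.12, and neither they nor the 4 liver genes were called. limma called 2356 genes under LFD (1286 higher, 1070 lower) and 3482 under HFD (2088 higher, 1394 lower). Without chow array 1 the counts were 155 and 811, and without chow array 2, which left array 1 as the only chow array, 5026 and 5359; in both the lone array was assumed to vary like the other groups. Without all 3 arrays that stood apart they were 365 and 1176.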

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

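The divisions of the arrays and the test with liver macrophages were planned before their results were seen. The other tests of the 3 patterns below were chosen after the patterns were seen.

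Among the groups of 4 arrays, 84 of 800 values (10.5%) of the named genes and array summaries lay apart from the other 3 arrays, where chance gives about 1 in 20. What set them apart was a gap to the nearest array, as a share of the group's range, above Dixon's 95% limit for 4 values. The number after each name is that share. HFD 8-week array 1 was lowest for Acaca 0.947, Ahsg 0.998, Alb 0.911, Cyp2a4 0.901, Cyp2b13 0.884, Cyp2f2 0.894, Elovl3 0.894, Gsta3 0.929, Hamp 0.925, Ivd 0.883, Mup20 0.937, Mup3 0.979, Serpina1d 0.968, Sugct 0.843, Ttr 0.953, Xist 0.85 and the mean of the hepatocyte genes 0.965. HFD 8-week array 1 was highest for Cd68 0.882, Col6a5 0.841, Ctsk 0.889, F7 0.947, Fos 0.83, Lipa 0.901, Otop1 0.886, Tm4sf19 0.83, Trem2 0.904 and Tyrobp 0.861. LFD 12-week array 3 was lowest for Alb 0.835, Apoe 0.875, Hamp 0.838, Hmgcs1 0.887, Lipa 0.893, Mtarc1 0.92, Mup20 0.83, Mup3 0.882, Serpina1d 0.83 and Ttr 0.84. HFD 12-week array 3 was lowest for Ahsg 0.906, Alb 0.98, Cyp2f2 0.962, Lcn10 0.833, Mup20 0.861, Mup3 0.926, Serpina1d 0.874, Ttr 0.944 and the mean of the hepatocyte genes 0.878. LFD 8-week array 4 was lowest for Apoe 0.865, Cyp2f2 0.855, Fam13a 0.95 and Peg3 0.841. LFD 8-week array 4 was highest for Ctss 0.917 and Sqle 0.959. LFD 4-week array 1 was lowest for Cyc1 0.857 and Insr 0.871. LFD 4-week array 1 was highest for Mrgprb1 0.913, Sult1e1 0.85, the mean of the epididymis genes 0.848 and the array median 0.92. HFD 8-week array 2 was lowest for Mki67 0.881 and the array median 1. HFD 8-week array 2 was highest for Fasn 0.846, Hsph1 0.889 and Nat8l 0.837. LFD 12-week array 1 was lowest for Col6a1 0.841, Hif1a 0.967 and Laptm5 0.915. LFD 12-week array 1 was highest for Lcn12 0.86. LFD 12-week array 4 was lowest for Wdr46 0.857. LFD 12-week array 4 was highest for Acss2 0.842 and Ppp1r3b 0.91. LFD 4-week array 2 was lowest for Cox8b 0.841. LFD 4-week array 2 was highest for Ccl2 0.855 and Peg3 0.866. HFD 8-week array 3 was lowest for H2-Eb1 0.941, Mtarc1 0.909 and Pparg 0.84. HFD 12-week array 2 was lowest for Itgam 0.935. HFD 12-week array 2 was highest for Adcy10 0.853. LFD 12-week array 2 was highest for Cox8b 0.909 and Saa3 0.925. LFD 4-week array 3 was highest for Cyp2f2 0.942. LFD 8-week array 2 was highest for Ighm 0.866. LFD 8-week array 1 was lowest for Mmrn1 0.831. HFD 8-week array 4 was lowest for Wdr46 0.831. HFD 8-week array 1, the only HFD array at 8 weeks without high hepatocyte transcripts, had the lowest values of liver genes such as Alb (10.46, the next 13.34) and the highest of macrophage genes such as Trem2 (9.32, the next 7.25).

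The first pattern was the hepatocyte transcripts of 11 arrays at 8 and 12 weeks, with 28 of 28 measured hepatocyte genes raised by 3.15 to 6.95 and a median rise of 4.78. The arrays were divided at the widest gap in the mean of these same genes, so a rise of their mean was fixed by the division. Examples were Alb (13.29 ± 0.20 in the 11 arrays and 8.89 ± 1.99 in the 14 others), Ahsg (12.19 ± 0.54 and 6.79 ± 1.45) and Hamp (12.16 ± 0.61 and 5.21 ± 1.99). Of the 28, 16 were above the median cluster level in the 14 others too, and no other list held any of the 28. Hepatocyte means in the 14 others reached 7.15, in LFD 12-week array 3, so levels in them do not show what fat alone expresses. A candidate explanation is RNA from liver in these samples, which the median rise of 4.78 leaves open. Diet or its duration acting on the tissue of each mouse would place a group's arrays together, but 4 of the 4 groups at 8 and 12 weeks held arrays of both kinds. Whether the RNA came from female mice cannot be told apart: Xist was higher, the median of 3 Y-linked genes differed by −0.13, and female-biased and male-biased liver genes rose by medians of 0.88 and 1.85 with wide spreads. Within LFD at 8 weeks, HFD at 8, LFD at 12 and HFD at 12 weeks, the Y-linked median differed by 0.08, 0.20, −0.23 and 0.12. In that order male-biased genes rose by 1.80, 2.25, 2.29 and 1.17 and female-biased ones by 1.01, 0.97, 1.26 and 0.62. These medians cannot decide about sex, since the 2 lists differ in their levels in the arrays without high hepatocyte transcripts. Of 10 genes in each, 6 male-biased and 0 female-biased ones were above the median cluster level in the 14 other arrays. Over all arrays the male-biased genes rose by 0.12 to 5.72 and the female-biased ones by 0.27 to 3.96. Xist rose by 1.75, 2.28, 2.57 and 1.39, which goes with a female source, whereas the Y-linked median fell only in LFD at 12 weeks. Of these groups, 3 had 1 array without high hepatocyte transcripts.

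The second pattern was the epididymis transcripts of chow array 1 and HFD 4-week array 1. A candidate explanation is RNA from epididymis, which lies beside gonadal fat. Of the 13 measured genes, 13 were over 1 higher in both arrays than in the 22 arrays that exclude LFD 4-week array 1. Gpx5 reached 13.60 and 13.21. The 2 arrays were picked by the mean of these same genes, and the array with the next highest mean was set aside. A rise of that mean was thus fixed by the choice. None of the 13 genes was above the median cluster level in those 22 arrays, and no other list held any. Chow diet or 4 weeks of HFD would raise the genes in the other arrays of these groups, whose highest mean exceeded the median of the remaining arrays by 0.0962.

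The third pattern was the rise of macrophage genes under HFD at 12 weeks (median 0.92 ± 0.12 over 20 genes). After a list median in this paragraph, ± is an error from the spread over the list's genes, taken as independent. It does not measure variation between mice. Liver macrophages arriving with liver RNA would raise their own genes, but 7 such genes had a median of −0.61 ± 0.15; 5 of the 7 were above the median cluster level in arrays without high hepatocyte transcripts. With the hepatocyte and epididymis means as covariates the macrophage median was 0.84, so liver transcripts that differed between the diets would not account for it. A lower share of adipocytes would raise every other cell type alike, but the highest median among endothelial, mast, smooth muscle, nerve and mesothelial cell lists was 0.15. These lists were chosen after the pattern was seen. Lists of fibroblasts, T cells, B cells and dendritic cells were not part of this comparison, and matrix genes also rose. An equal rise of all cell types was thus not seen, but whether a lower share of adipocytes made up part of the rise was not tested. A response of the tissue to HFD, by more macrophages or by more transcript in each, stays open as a hypothesis found on the same data.

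Other divisions of the compared arrays into groups of the same sizes were fitted. At 8 weeks 1 of the 35 splits, the real one, called as many genes (533, highest other 1). The same held at 12 weeks (1 of 35, 989, highest other 1) and for the average (1 of the 100, 2322, highest other 1). It held too for LFD at 8 against 4 weeks (1 of the 35, 141, highest other 0) and at 12 against 4 weeks (1 of the 35, 151, highest other 3). HFD at 12 against 4 weeks gave 1 of the 35 (127, highest other 1). With 35 splits, 1 of 35 is the smallest share possible. Splits that mix the groups also add the real difference to the spread, which lowers their counts. Chance is thus made less likely, not excluded. The 3 time comparisons in part followed the hepatocyte split (correlation 0.58, 0.77 and 0.75) and called 0, 14 and 5 genes on their own groups. Their calls cannot be set down to time alone. At 4 weeks 2 of the 35 splits called as many genes as the real 47, the other calling 53 with LFD array 2 joined to the HFD arrays, so chance cannot be excluded there. For HFD at 8 against 4 weeks (35 splits) and for the interaction (100 splits) the real division called 0 genes. Any split reaches 0, so these tests cannot decide about chance. For HFD at 8 against 4 weeks the highest other, 196, parted HFD 8-week arrays 2, 3 and 4 from the rest, the arrays with high hepatocyte transcripts. For the interaction the highest other called 181.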

How the results depend on the processing

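Alternatives that use the hepatocyte split, the covariates or the removal of 3 arrays were chosen after the data were seen. Numbers are called genes, given where they differ by over 1.5 times from the counts in the report. Fitted on the compared groups alone (fewer arrays to estimate the spread), calls numbered 0 for 4 weeks, 0 for LFD 8 against 4 weeks, 14 for LFD 12 against 4 weeks, 5 for HFD 12 against 4 weeks, 747 for LFD against chow and 2042 for HFD against chow. With quantile normalization, calls numbered 1 for HFD 8 against 4 weeks. With arrays centred on their medians, calls numbered 313 for 8 weeks, 276 for LFD 8 against 4 weeks and 82 for HFD 12 against 4 weeks. Without dim genes (fewer genes tested), calls numbered 76 for 4 weeks, 291 for LFD 8 against 4 weeks and 3 for HFD 8 against 4 weeks. With all clusters tested, calls numbered 400 for LFD 8 against 4 weeks, 701 for LFD 12 against 4 weeks and 254 for HFD 12 against 4 weeks. With an intensity trend and robust moderation, calls numbered 1 for HFD 8 against 4 weeks. With array weights, calls numbered 163 for 4 weeks, 1267 for 8 weeks, 1787 for 12 weeks, 465 for LFD 8 against 4 weeks, 1335 for LFD 12 against 4 weeks, 7 for HFD 8 against 4 weeks, 260 for HFD 12 against 4 weeks, 10 for LFD against chow and 75 for HFD against chow. With replicate number as a block, calls numbered 222 for LFD 8 against 4 weeks, 1 for HFD 8 against 4 weeks and 73 for HFD 12 against 4 weeks. With an added fold limit of 1.5, calls numbered 596 for the average and 89 for LFD 8 against 4 weeks. The analysis of variance with unadjusted p and the fold limit gave 466 for 4 weeks, 814 for 8 weeks, 620 for the average, 571 for the interaction, 505 for LFD 8 against 4 weeks, 892 for LFD 12 against 4 weeks, 563 for HFD 8 against 4 weeks and 578 for HFD 12 against 4 weeks. The analysis of variance with adjustment gave 31 for 4 weeks and 52 for HFD 12 against 4 weeks. The parentheses describe the fits, and the cause of these differences was not tested. Fewer arrays did not lower every count: fitted alone, the groups at 12 weeks gave 1292 calls against 989.

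With the hepatocyte split as a block, calls numbered 81 for the interaction, 33 for LFD 8 against 4 weeks, 19 for LFD 12 against 4 weeks, 1 for HFD 8 against 4 weeks and 213 for HFD 12 against 4 weeks. With the hepatocyte and epididymis means as covariates, calls numbered 233 for 4 weeks, 970 for 8 weeks, 22 for LFD 12 against 4 weeks, 4 for HFD 8 against 4 weeks, 309 for HFD 12 against 4 weeks, 132 for LFD against chow and 1342 for HFD against chow. Without the 3 arrays that stood apart, calls numbered 1251 for 8 weeks, 1865 for 12 weeks, 92 for LFD 8 against 4 weeks, 99 for LFD 12 against 4 weeks, 15 for HFD 8 against 4 weeks, 365 for LFD against chow and 1176 for HFD against chow. Without those arrays and with the block, calls numbered 79 for 4 weeks, 1590 for 8 weeks, 2534 for 12 weeks, 217 for the interaction, 31 for LFD 8 against 4 weeks, 50 for LFD 12 against 4 weeks, 8 for HFD 8 against 4 weeks, 334 for HFD 12 against 4 weeks, 374 for LFD against chow and 1440 for HFD against chow. On arrays with high hepatocyte transcripts alone, calls numbered 211 for 8 weeks and 1800 for 12 weeks. On the other arrays alone, calls numbered 0 for 4 weeks, 38 for 8 weeks, 0 for 12 weeks, 288 for the average, 0 for LFD 8 against 4 weeks, 0 for LFD 12 against 4 weeks, 17 for HFD 8 against 4 weeks, 20 for HFD 12 against 4 weeks, 28 for LFD against chow and 912 for HFD against chow. Fits on one side of the split hold fewer arrays: the other arrays were 1 HFD and 2 LFD arrays at 8 weeks and 1 of each diet at 12 weeks. A lone array was assumed to vary like the other groups, so nothing is concluded from those counts. The cause of the other differences was not tested.

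Leaving out 1 array at a time gave 2 to 100 for 4 weeks, 164 to 438 for 8 weeks, 558 to 944 for 12 weeks, 1793 to 2527 for the average, 0 to 0 for the interaction, 22 to 224 for LFD 8 against 4 weeks, 28 to 639 for LFD 12 against 4 weeks, 0 to 2 for HFD 8 against 4 weeks, 4 to 175 for HFD 12 against 4 weeks, 155 to 5026 for LFD against chow and 811 to 5359 for HFD against chow. Over these fits, 731 values of called named genes were no longer called and 7 changed sign, and 5 values of named genes not called became called. Sign changes of genes not called were not counted.

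Called genes changed sign only without chow array 1, for epididymis genes against chow, whose ranges were Rnase9 −9.39 to 0.041 and Defb39 −8.78 to 0.005 under LFD, and Defb12 −8.01 to 0.37, Defb38 −7.48 to 0.32, Lcn12 −6.93 to 0.12, Clpsl2 −7.03 to 0.26 and Lcn10 −6.66 to 0.12 under HFD; the epididymis list against chow under HFD ranged over −7.88 to 0.60. At 4 weeks the epididymis list ranged over −0.47 to 2.81, negative without HFD array 1, and was −0.10 without the 3 arrays that stood apart, with or without the block. The endothelial list ranged over −0.063 to 0.41 at 4 weeks, negative without LFD array 1. These arrays carried the epididymis transcripts.

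The 172 list results include lists that were not called and so had no call to lose. Of them, 77 were no longer called with an estimated correlation, 29 with fry and 10 with the covariates. The number was 8 without the 3 arrays and with the block, 6 without the 3 arrays and 5 with the block. It was 4 with quantile normalization, 2 with array weights, 1 with centring and 1 with replicate number as a block. Under HFD, camera called 9 lists up and 4 down at 4 weeks and 11 and 9 at 8 weeks. It called 13 and 12 at 12 weeks, and 13 and 10 in the average. With an estimated correlation 0, 5, 8 and 9 stayed called. Newly called results numbered 7 with array weights, 6 with fry, 5 with the covariates and 5 without the 3 arrays. Leaving out 1 array at a time lost 50 calls and gained 35. Of the lists still large enough without dim genes, 7 were no longer called. Higher genes made up 89.4% of calls at 4 weeks and 74.5% with quantile normalization, 48.6% at 8 weeks and 34.5% with centring, 73.8% for LFD at 8 against 4 weeks and 55.7% and 91.3% with these, and 43.7% for LFD at 12 against 4 weeks and 28.3% with quantile normalization. Whether replicate numbers pair the LFD and HFD arrays cannot be told. Of 11 same-number pairs at the same time, correlations after removing group means ran from −0.61 to 0.60 and 5 were over 0.1. The highest, 0.60, was between LFD and HFD 12-week arrays 3, both without high hepatocyte transcripts. Transcripts of other tissues thus enter these correlations. Signal over background was not analysed here, and 13090 genes lay above the limit of 5.13 for dim genes.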

Other observations

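Genes of the circadian clock, which drives daily rhythms in fat cells, moved in opposite directions under HFD. Averaged over the 3 times, 8 of 15 fell and 3 rose (11 and 3 adjusted over the list alone), with Per3 (−1.17 ± 0.13), Dbp (−1.20 ± 0.16) and Tef (−0.89 ± 0.12) lower and Arntl, which encodes BMAL1, higher (1.09 ± 0.13). The list's median was −0.44 (adjusted p = 1.18e-04; adjusted p = 0.0414 with an estimated correlation). Per3 averaged 8.96 ± 0.27 under LFD and 7.54 ± 0.14 under HFD at 8 weeks (n = 4 and 4). The hour of tissue collection is not given in the sources used here, so a difference in rhythm was not tested. Among immediate early and heat shock genes, which respond within minutes to stress, 3 of 15 rose (6 adjusted over the list alone): Atf3 (1.10 ± 0.16), Fos (0.68 ± 0.17) and Hsph1 (0.45 ± 0.13) (adjusted p = 3.02e-04; adjusted p = 0.129 with an estimated correlation). Hsph1 was not called without HFD 4-week array 3.

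Genes of further lists changed under HFD in the average over time (11 and 12 arrays). Of 17 glutathione and oxidative stress genes, 5 fell and 3 rose: the glutathione transferase genes Gsta4 (−1.08 ± 0.12) and Gsta3 (−0.91 ± 0.22) and the superoxide dismutase gene Sod1 (−0.32 ± 0.06) were lower, and Hmox1, heme oxygenase 1, was higher (0.66 ± 0.14), with no call of the list (adjusted p = 0.164). In the hypoxia and glycolysis list 4 of 13 genes fell, as Pdk1 (−0.90 ± 0.11) and Hk2 (−0.54 ± 0.12), while Hif1a (0.35 ± 0.08) and Adm (0.46 ± 0.12) rose (adjusted p = 0.0204; adjusted p = 0.195 with an estimated correlation). Pdk1 was at −0.58 as the mean of its clusters. Thermogenic genes fell in 3 of 11 cases, with Cidea (−0.83 ± 0.13), Ppargc1a (−0.71 ± 0.11) and Cox8b (−0.49 ± 0.12), whereas the proton channel gene Otop1 rose (0.81 ± 0.16), and the list was not called (adjusted p = 0.266). Of 10 mast cell genes, 3 fell, Cpa3 (−0.59 ± 0.15), Mrgprb1 (−0.46 ± 0.13) and Tpsb2 (−0.41 ± 0.13) (adjusted p = 0.0172; adjusted p = 0.195 with an estimated correlation), and Mrgprb1 and Tpsb2 lost their calls without 6 and 12 of the 23 arrays. Adjusted over the list alone, 5, 7, 3 and 3 genes of these lists fell.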
